A study of Caenorhabditis elegans with 60 samples.

How the data were processed

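Messenger RNA of whole wild-type N2 (Bristol) worms of Caenorhabditis elegans was profiled after 48 h of exposure, from the synchronised first larval stage, to hexafluoropropylene oxide dimer acid (HFPO-DA). Per the labels' protocols, each sample was a well of about 1000 pooled worms in liquid culture with E. coli HB101 as food, the concentrations were placed at random on 12-well plates, RNA was isolated over 2 days, and poly(A) RNA was sequenced at shallow depth. The groups were taken from the sample titles: 14 concentrations from 0.0125 to 4000 mg/L and 1 control, with 4 replicates in each of the 15 groups and 60 libraries in all. The replicates are separate wells. Nothing in the labels says that they came from separate worm cultures, so p-values measure the spread between wells.

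The deposited table holds a normalised signal per gene on a linear scale for 10298 genes, which are not read counts. The submitters' processing notes name UMI-tools 1.1.2, Trimmomatic 0.39, STAR 2.7.10a, HTSeq 2.0.1, edgeR 3.36.0 and the build WBcel235, with no role or order, and the steps from reads to these values are not given in the sources used here. The values themselves show part of those steps. Each deposited value equals 1 plus a factor times the sum of 1 and the library's scaled read number. That factor belongs to 1 gene and 1 replicate number, is shared by 15 libraries and lies between 0.445 and 3.18. Reads of 0 are held as 0.5. With these factors 100% of the 617880 values gave whole reads within a tolerance of 0.0001 reads, and 1.07% were reads of 0. The recovery was tested on simulated tables of 6000 genes and returned the simulated reads in 100% of 360000 values. The factor per replicate number also means that differences between replicate numbers had been adjusted for in the deposited values, and 2 of the 3 dimensions of the replicate-number means have no spread left.

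Depth was taken from the recovered reads. Libraries held 462117 to 4522107 reads over the listed genes (median 1475652.5), the control libraries 999346 to 1914706 and the 4 g/L libraries 737039 to 1249951. Fold changes are on the log2(value + 1) scale, which understates the change of genes with few reads. Counting intervals are exact binomial 95% intervals of the ratio of reads over size factors, pooled over the 4 libraries of a group. Lower bounds use 3 reads over the group as the floor. Both cover counting error only.

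Values were tested as log2(value + 1) for the 10293 genes that reached a value of 5 in at least 4 libraries. limma 3.58.1 in R 4.3.3 was used with an intensity trend, 15 group means in 1 fit, and the contrast of each concentration with the control. p-values are two-sided and were adjusted by the Benjamini-Hochberg method over all genes of a contrast, with a threshold of 0.05 and no limit on the fold. A second model fitted 1 slope per gene over the rank of the concentration (0 for the control to 14). A lasting call is the lowest concentration from which a gene was called in the same direction at every higher one. Gene symbols and positions came from the annotation of WBcel235, which matched 10294 of the identifiers. Of 37 gene lists, 36 had at least 3 measured genes and were tested with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation and fry beside it. The mitochondrially encoded genes had 0 measured members. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for tables and plots.

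The groups, models, thresholds, lists, many alternative settings and the rule for named genes were fixed before the data were examined. Named genes are the 8 rising and 8 falling genes with the largest called change at 4 g/L, and up to 4 and 4 at 2, 1 and 0.5 g/L, with a letter-number name, a mean of at least 20 and all 4 treated libraries beyond all controls. They also include all called genes at a lower concentration where 5 or fewer were called (otherwise the 3 with the smallest p), the 4 rising and 4 falling genes with the smallest trend p, and up to 3 called members of each list. Where a list had no called member, its 2 members with the highest mean were named. Values are printed for part of the genes so selected, and some are not reported here. Other genes named below were chosen after their values were seen.

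Sets of 12 consecutive sample numbers, found in the data, were used as an additive term on the reads over the size factor. This fit, voom on the recovered reads, fits without 3 libraries of large residual spread (over 1.4 times the median), reads thinned to 462117 per library, the split of the controls between comparisons, and the other added settings were chosen after seeing the data. No pair of replicates within a group agreed within sampling noise: the lowest dispersion over 90 pairs was 1.96 times that noise.

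The models were tested on simulated tables with known changes. These tables held no factor per gene and replicate number. The rates below therefore need not hold for the deposited values, where that factor had adjusted for the replicate numbers. At 4 g/L the model recovered 26.9% of 67 genes changed by a fold of 1.5, 62.7% of 67 at a fold of 2 and 89.4% of 66 at a fold of 4, and called 14 of the 10271 genes wrongly, a larger share of the calls than the threshold of 0.05 names. It called 0 genes at the 13 lower concentrations, where none had been changed. With differences between sets simulated as well, the model without a set term recovered 16.4%, 53.7% and 81.8% at these folds and called 1 unchanged gene. With the set term it recovered 26.9%, 61.2% and 90.9% and called 14 unchanged genes. The slope model recovered 87% of genes with a total log2 change of 1 and 99% with 2, and called 9 unchanged genes. Genes of the cyp-13A, col, msp, vit, his, fipr and ugt families have close copies, and how reads shared by copies, overlapping genes or antisense partners were counted is not given in the sources used here, so values of single members are uncertain to that extent.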

Results

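The study asked how gene expression in developing worms changes with the concentration of HFPO-DA, a perfluorinated ether acid used in making fluoropolymers. Whole worms were sampled in 15 groups of 4 libraries, the control and 14 concentrations from 0.0125 to 4000 mg/L. Recovered depth ranged from 462117 to 4522107 reads per library. The 4 g/L libraries were shallower (median 890603 reads) than the controls (median 1472382).

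At 4 g/L the largest rises were in a cluster of cytochrome P450 genes, oxidising enzymes of xenobiotic metabolism. The cyp-13A7 gene (CELE_T10B9.10, chromosome II, 9803620 to 9805513, WBcel235) had deposited values of 2.43 to 3.17 in the 4 controls and 1144 ± 108 (SD, n = 4) at 4 g/L, a log2 fold change of 8.27 ± 0.22 (SE, limma adjusted p = 9.43e-37). Its 4 control libraries together held 1 read and its treated libraries 2884, a ratio of 4315 with a counting interval of 774 to 170484. Its neighbour cyp-13A6 (CELE_T10B9.3, II, 9800758 to 9802821) rose from 0 reads in the 4 controls to 1297 reads, at least 647-fold higher against a floor of 3 reads over the group. cyp-13A4 (II, 9795756 to 9797740) also had 0 control reads and was at least 208-fold higher. cyp-13A5, in the same cluster, had a log2 fold change of 4.56 ± 0.27 (SE), and cyp-13A2 one of 0.95 ± 0.30 (limma adjusted p = 0.0149, and 0.0643 with the set term). Of 34 measured cytochrome P450 genes 9 rose and 8 fell (10 and 9 adjusted over the list alone). Their list was called up with the preset correlation (camera adjusted p = 0.000863) and not with an estimated one (adjusted p = 0.249 with an estimated correlation).

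Many genes of conjugating enzymes also rose. Of 37 genes named as UDP-glucuronosyltransferases, which attach sugar groups to foreign compounds, 17 rose and 4 fell (18 and 4 adjusted over the list alone). The list was called up with either correlation (adjusted p = 1.2e-07, and adjusted p = 0.00168 with an estimated correlation). ugt-19 (IV, 6076686 to 6079952) went from 6.39 ± 1.12 to 193 ± 15.2 (SD, n = 4), a log2 fold change of 4.72 ± 0.27 (SE, limma adjusted p = 1.06e-20). ugt-62 had a log2 fold change of 3.23 ± 0.18 and ugt-61 one of 3.13 ± 0.31. Of 27 glutathione S-transferases 8 rose and 3 fell (12 and 3 adjusted over the list alone), with gst-5 at 2.59 ± 0.18 and gst-8 at least 28.9-fold higher than its 0 control reads. Their list was called up (adjusted p = 0.0217, and adjusted p = 0.251 with an estimated correlation). Among 16 ABC exporters 4 rose and 1 fell (4 and 1 adjusted over the list alone), led by pgp-1 with 3 control reads and 146 treated reads, a ratio of 72.8 with a counting interval of 24.4 to 357. That list was not called by camera (adjusted p = 0.11) and was by fry, which compares no list with other genes (adjusted p = 1.68e-05). The cadmium-inducible cdr-1 rose by 4.18 ± 0.23 on the log2 scale and the lysosomal lipid carrier lbp-8 was at least 36.9-fold higher than its 0 control reads.

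**Figure D1:**
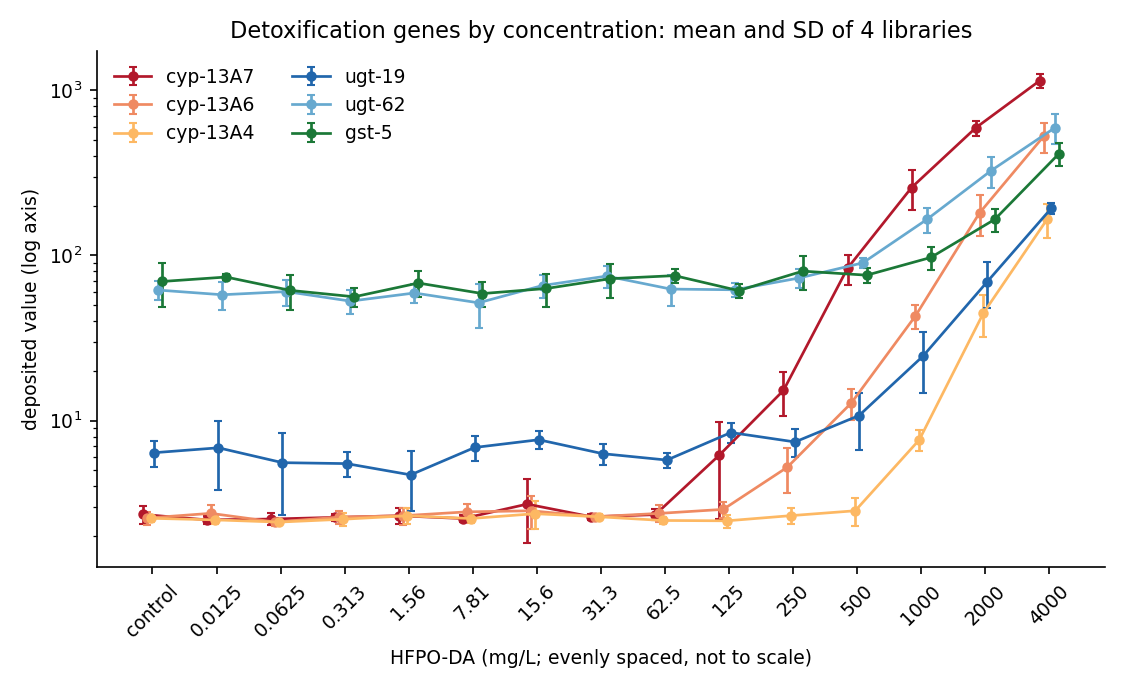
Mean deposited value (log axis) of 6 detoxification genes against the concentration of HFPO-DA in mg/L, with bars for the SD of 4 libraries. cyp-13A7 lay between 2.43 and 3.17 in the controls and rose to 15.2 at 250 mg/L and 1144 at 4000 mg/L, while gst-5 stood at 69.6 in controls and 413 at 4000 mg/L.

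Many genes of the cuticle and some of sperm rose at 4 g/L. Of 96 cuticle collagens 64 rose and 9 fell (65 and 9 adjusted over the list alone), with a median log2 fold change of 1.39. col-146 had a log2 fold change of 4.83 ± 0.69 (SE, limma adjusted p = 7.45e-07), col-39 of 4.56 ± 0.78 and col-161 of 4.42 ± 0.62. These collagens varied widely between wells, col-146 standing at 951 ± 1093 (SD, n = 4) at 4 g/L. col-101 went the other way, from 1481 ± 439 to 427 ± 292 (SD, n = 4), and col-95 fell by 1.66 on the log2 scale. The collagen list was called up (adjusted p = 8.26e-13, and adjusted p = 0.249 with an estimated correlation). Of 80 sperm genes 26 rose and 0 fell (26 and 0 adjusted over the list alone, and 58 and 0 with the set term on the reads), with the major sperm protein gene msp-74 at 1.41 ± 0.32 (SE). Their list was called up (adjusted p = 7.53e-09, and adjusted p = 0.452 with an estimated correlation).

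Many genes of yolk, oocytes and the proteasome fell at 4 g/L. Of 6 vitellogenins, the yolk proteins made in the adult intestine, 4 fell and 0 rose (6 fell adjusted over the list alone). vit-3 went from 3838 ± 793 to 1429 ± 664 (SD, n = 4), a log2 fold change of -1.53 ± 0.25, and vit-1 fell by 1.48 on the log2 scale. Of 27 oocyte and eggshell genes 17 fell and 0 rose (20 fell adjusted over the list alone), with cpg-3, an eggshell proteoglycan, at -0.87 ± 0.16 and oma-2, a regulator of oocyte maturation, at -0.81 ± 0.16. Of 31 proteasome subunits 22 fell and 0 rose (23 fell adjusted over the list alone), by small amounts such as -0.61 ± 0.11 for pas-2 and -0.59 ± 0.12 for rpn-9. Of 31 germ line genes 6 fell and 0 rose (5 fell adjusted over the list alone), among them syp-2, part of the synaptonemal complex, at -0.68 ± 0.17. The lists were called down, the vitellogenins with adjusted p = 0.00011, oocyte genes with adjusted p = 7.53e-09, the proteasome with adjusted p = 1.22e-08 and germ line genes with adjusted p = 0.0213. With an estimated correlation none was called (adjusted p = 0.251, 0.251, 0.249 and 0.452 with an estimated correlation, in that order).

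Among tissue lists at 4 g/L, 10 of 17 intestine markers rose and 2 fell (11 and 2 adjusted over the list alone), with the intermediate filament gene ifb-2 at 1.68 ± 0.22 and the ferritin gene ftn-1 at -1.42 ± 0.34. Of 23 muscle markers 9 rose and 0 fell (9 and 0 adjusted over the list alone), such as unc-89, a giant protein of the sarcomere, at 1.02 ± 0.23. Of 20 vacuolar ATPase subunits 9 rose and 0 fell (13 and 0 adjusted over the list alone), with vha-6 at 0.85 ± 0.13. Of 85 neuropeptides 15 rose and 0 fell (10 and 0 adjusted over the list alone), and of 18 neuron markers 4 rose and 0 fell (4 and 0 adjusted over the list alone), with egl-3 at 1.05 ± 0.24. With the set term the intestine, muscle, vacuolar ATPase and neuropeptide lists were called up as well and neuron markers were not (adjusted p = 0.121). Adding an estimated correlation to the set term left the intestine list called (adjusted p = 0.0265) and the muscle, vacuolar ATPase and neuropeptide lists not called (adjusted p = 0.296, 0.179 and 0.203). The 5 lists were called up, intestine with adjusted p = 0.000117, muscle with adjusted p = 0.000115, the vacuolar ATPase with adjusted p = 0.000129, neuropeptides with adjusted p = 0.000139 and neurons with adjusted p = 0.0368. With an estimated correlation none was called (adjusted p = 0.249, 0.424, 0.249, 0.251 and 0.249 with an estimated correlation, in that order).

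**Figure D2:**
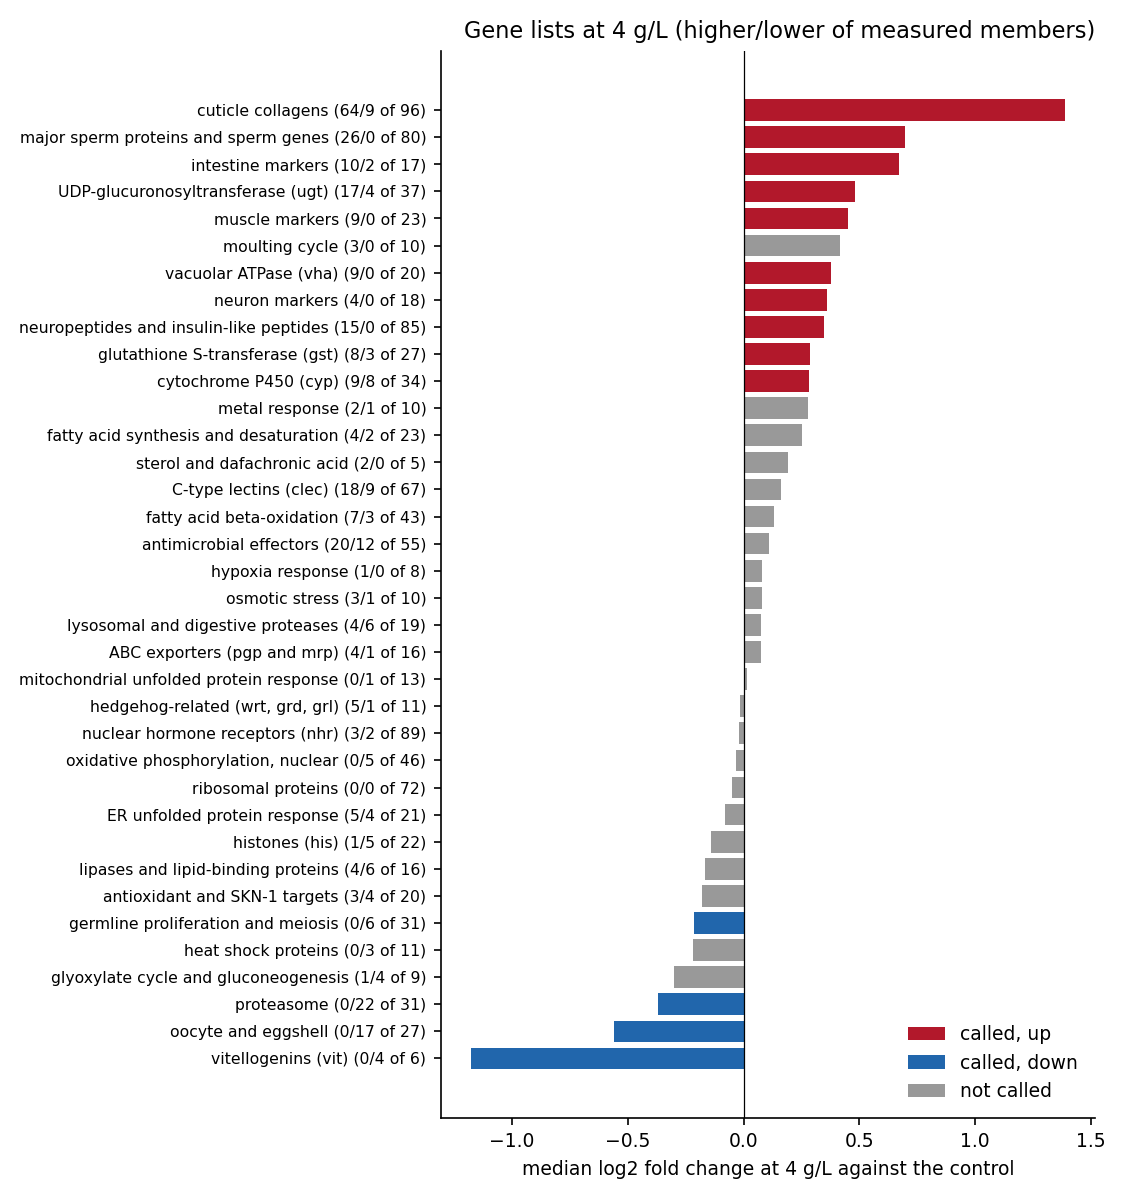
Median log2 fold change at 4 g/L against the control for 36 gene lists, with the number of members that rose and fell after each name. Red and blue bars are lists called up and down by camera with the preset correlation, and grey bars are lists that were not called. Cuticle collagens had the highest median at 1.39 and vitellogenins the lowest at -1.18.

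The other lists at 4 g/L were not called by camera, and most held members that moved each way. Antimicrobial effectors had 20 of 55 higher and 12 lower (21 and 13 adjusted over the list alone), from fipr-4 at 3.88 ± 0.58 to spp-17, a saposin-like gene, at -1.78 ± 0.21, and the list was called up with the set term (adjusted p = 0.027, and adjusted p = 0.406 with an estimated correlation). C-type lectins had 18 of 67 higher and 9 lower (21 and 12 adjusted over the list alone), lysosomal proteases 4 of 19 and 6 (4 and 6 adjusted over the list alone), and lipases and lipid-binding proteins 4 of 16 and 6 (4 and 7 adjusted over the list alone). The lipase list had a median of -0.17 and a mean of 0.10, and the protease list a median of 0.08 against a test direction of down. Fatty acid breakdown had 7 of 43 higher and 3 lower (7 and 3 adjusted over the list alone) and fatty acid synthesis 4 of 23 and 2 (5 and 3 adjusted over the list alone), where the desaturase gene fat-7 fell by 1.51 on the log2 scale. Hedgehog-related genes had 5 of 11 higher and 1 lower (5 and 1 adjusted over the list alone), with grl-21 at 3.87 ± 0.42 and a list median of -0.02 against a test direction of up. Osmotic stress genes had 3 of 10 higher and 1 lower (3 and 2 adjusted over the list alone), with hmit-1.1 at 1.88 ± 0.31. Metal response genes had 2 of 10 and 1 (2 and 1 adjusted over the list alone), and moulting genes 3 of 10 and 0 (3 and 0 adjusted over the list alone). The 3 moulting genes, qua-1, lin-42 and mlt-8, were not called with the set term (adjusted p = 0.0749, 0.0584 and 0.224). fry called 24 of the 36 lists at 4 g/L, among them the antimicrobial, C-type lectin, fatty acid breakdown, hedgehog-related, osmotic, metal and moulting lists and those of heat shock genes and histones.

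The lists of heat shock, unfolded protein response and antioxidant genes were not called by camera at 4 g/L. Heat shock genes had 0 of 11 higher and 3 lower (0 and 3 adjusted over the list alone), with hsp-12.3 at -1.12 ± 0.28 and sip-1 at -0.54 ± 0.17. The unfolded protein response of the endoplasmic reticulum had 5 of 21 higher and 4 lower (5 and 4 adjusted over the list alone), from the co-chaperone gene dnj-7 at 1.03 ± 0.22 to dnj-27 at -0.93 ± 0.22, with a median of -0.08 against a test direction of up, and that of mitochondria 0 of 13 and 1 (0 and 1 adjusted over the list alone). Antioxidant genes had 3 of 20 higher and 4 lower (3 and 4 adjusted over the list alone), with gpx-1 at 1.17 ± 0.21. Counts for the rest were 1 and 0 of 8 hypoxia genes, 2 and 0 of 5 sterol genes, 1 and 4 of 9 glyoxylate cycle genes, 1 and 5 of 22 histones and 0 and 5 of 46 respiratory chain genes, and each was the same adjusted over the list alone except the respiratory chain (0 and 3). Nuclear hormone receptors had 3 of 89 higher and 2 lower (0 and 1 adjusted over the list alone), with a median of -0.02 and a mean of 0.02. Of 72 ribosomal protein genes 0 rose and 0 fell in the limma fit (0 and 0 adjusted over the list alone; 0 and 1 with the set term on reads), with rps-24 at -0.04 ± 0.10.

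Over all 10293 genes at 4 g/L, 1518 rose and 1414 fell (limma, Benjamini-Hochberg), 2932 in all, with a median log2 fold change of -0.05. The share of calls that were higher, 51.8%, was 57.7% with median ratio rescaling, 43.5% with quantile normalization, 42.4% among genes reaching 20 and 45.0% on reads over the size factor. The short-chain dehydrogenase gene dhs-26 had the largest fall by the naming rule, from 167 control reads to 2 treated reads, a ratio of 0.0179 with a counting interval of 0.00215 to 0.0657. Next were dod-3 at -2.13 ± 0.39, col-101, spp-17, col-95, drd-10, clec-222 and vit-3. With the set term on the reads 1602 rose and 1474 fell, and 2655 of the 2932 genes (90.6%) were called in the same direction. In the 3 sets that held a control and a 4 g/L library, the control libraries held 1, 0 and 0 reads of cyp-13A7 and the 4 g/L libraries 538, 548 and 1061, and the lower bounds of the counting intervals of the fold were 177, 325 and 337. The log2 difference of dod-3 was 0.10 in 1 set and -2.64 and -2.81 in the others. The count fell to 1817 without control replicate 2 and to 1303 without replicate 4 at 4 g/L, and voom on the reads called 1781.

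At 2 g/L genes of the cyp-13A cluster and of conjugating enzymes rose. cyp-13A7 reached 592 ± 61.4 and cyp-13A6 181 ± 49.8 (SD, n = 4), at least 226-fold higher than its 0 control reads. ugt-19 had a log2 fold change of 3.20 ± 0.27 (SE, limma adjusted p = 1.73e-13), ugt-62 of 2.37 ± 0.18 and gst-5 of 1.27 ± 0.18. Falling genes by the naming rule were dhs-26 at -1.70 ± 0.27, gst-29 at -1.25 ± 0.27, ugt-44 at -1.18 ± 0.28 and the glucosylceramidase gene gba-4 at -0.91 ± 0.16. Of the 10293 genes 32 rose and 18 fell, against 45 and 21 with the set term, where ugt-44 was not called (adjusted p = 0.073). Of 34 cytochrome P450 genes 7 rose and 1 fell (7 and 1 adjusted over the list alone), and the list was called up although its median was -0.09 and its mean 0.57 (adjusted p = 3.12e-06, and adjusted p = 0.0189 with an estimated correlation). Of 37 UDP-glucuronosyltransferases 6 rose and 1 fell (10 and 3 adjusted over the list alone), called up with adjusted p = 5.77e-06 (adjusted p = 0.00792 with an estimated correlation). With the preset correlation 9 lists were called, and the other 7, among them the proteasome (down) and cuticle collagens (up), were not called with an estimated one (smallest adjusted p = 0.394 with an estimated correlation). Without replicate 4 at 2 g/L 5 lists were called.

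At 1 g/L 16 genes rose and 1 fell. cyp-13A7 stood at 258 ± 69.5 and cyp-13A6 at 43.0 ± 7.10 (SD, n = 4), and ugt-62 at 165 ± 29.1 against 61.7 ± 8.32 in controls (SD, n = 4; limma adjusted p = 3.08e-07). ugt-19 had a log2 fold change of 1.69 ± 0.27 (SE). The falling gene was R08F11.4 at -0.91 ± 0.19. Of the cytochrome P450 genes 6 of 34 rose and 0 fell (7 and 1 adjusted over the list alone). Their list was called up although its median was -0.12 (adjusted p = 2.67e-05, and adjusted p = 0.0649 with an estimated correlation). It was called with both the set term and an estimated correlation (adjusted p = 0.0498) and by fry (adjusted p = 9.64e-06). With the set term 15 genes were called, and cyp-33C2 (adjusted p = 0.126), cyp-33E3 (adjusted p = 0.148) and ugt-63 (adjusted p = 0.0548) were among those lost.

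At 500 mg/L 2 genes rose and 0 fell: cyp-13A7 at 83.7 ± 17.3 (SD, n = 4) and cyp-13A6 with 45 reads, at least 13.8-fold higher than its 0 control reads. At 250 mg/L the 1 called gene was cyp-13A7 at 15.2 ± 4.57 (SD, n = 4), with 50 treated reads against 1 control read, a ratio of 48.3 with a counting interval of 8.29 to 1947. With the set term cyp-13A6 was also called at 250 mg/L (adjusted p = 0.00465), while reads thinned to 1 depth with the set term gave 0 calls at 250 mg/L and 1 at 500 mg/L. Without replicate 4 at 250 mg/L 2 genes were called there. At an unadjusted p of 0.05 limma passed 505 and 294 genes at these concentrations (4.91% and 2.86%), where a share of about 0.05 would pass with no change. voom called 2 and 1.

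From 0.0125 to 125 mg/L limma called 0 of 10293 genes at each of the 9 concentrations. Between 294 and 677 genes (2.86% to 6.58%) had an unadjusted limma p under 0.05, where a share of about 0.05 would pass with no change. voom called 0 at each. The exception when 1 library was left out was 1.56 mg/L, with 1 gene without control replicate 1. cyp-13A7 was at 6.19 ± 3.65 (SD, n = 4) at 125 mg/L, a difference from the control that was not called (adjusted p = 1.00). Its log2 fold change there was 0.81 ± 0.22 (SE), and 1.59 with the set term, also not called. Its libraries at 125 mg/L ranged from 2.60 to 10.4, against 2.43 to 3.17 in the controls, so a rise below 250 mg/L is not excluded. Between 1 and 10 lists per concentration were called with the preset correlation, with medians such as 0.31 for vitellogenins and -0.25 for sperm genes at 125 mg/L, against -1.18 and 0.70 at 4 g/L. With an estimated correlation 0 lists were called by camera at these concentrations, and fry called 0.

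Of the genes called at 4 g/L, 48 had a lasting call from a lower concentration. cyp-13A7 was called from 250 mg/L upward and cyp-13A6 from 500 mg/L. From 1 g/L upward 14 genes were called, 13 higher and 1 lower, among them cyp-13A4, cyp-13A5, ugt-19, ugt-62, ugt-63, cdr-1, lbp-8 and the apyrase gene apy-1. A further 32 genes were called from 2 g/L upward, 16 higher and 16 lower, including gst-5, gst-8, pgp-1, dhs-26 and the lipase gene lipl-5. The remaining 2884 genes had a lasting call from 4 g/L. With the set term on the reads, 2 genes had a lasting call from 250 mg/L, 0 from 500 mg/L and 12 from 1 g/L. A further 49 had one from 2 g/L with that term, 32 higher and 17 lower. Comparisons at 2 and 4 g/L share their controls, and 31 rising and 17 falling genes were called at both, where independent lists of these lengths would share 4.72 and 2.47. Unchanged groups simulated against the same controls shared 0 in each of 20 runs. These runs drew each gene independently and without differences between sets. They therefore cannot decide whether sets, or spread common to many genes, add to the shared calls. With the controls split between the comparisons, 2 libraries each, 22 to 27 rising and 3 to 10 falling genes were called at both over the 6 ways to split them.

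Over the rank of the concentration 391 genes rose and 285 fell. The slope per rank was 0.57 ± 0.05 (SE, limma adjusted p = 6.44e-15) for cyp-13A7, 0.40 ± 0.04 for cyp-13A6, 0.24 ± 0.03 for ugt-19 and 0.18 ± 0.02 for ugt-62. Falling slopes were those of dhs-26 at -0.15 ± 0.02, gba-4 at -0.05 ± 0.01, and the acid phosphatase genes acp-6 at -0.05 ± 0.01 and pho-11 at -0.04 ± 0.01. Of the 36 lists 13 were called, 9 up and 4 down, and 0 with an estimated correlation (smallest adjusted p = 0.365 with an estimated correlation), while fry called 10. The count of 676 genes rested on the highest concentration, with 32 called without the 4 g/L libraries. It was 1069 with the set term on the reads (726 higher, 343 lower), 304 on the reads without it, 156 with voom and 88 with library weights, and moved to 125, 226, 1588 and 1697 without the 15 libraries of replicate number 2, 4, 1 and 3.

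The libraries also differed by their sample number. In libraries at the concentrations without calls and in the controls, the first principal component (27.8% of the variance over all libraries) averaged 27.5, 14.8 and 27.6 in the sets numbered 1 to 12, 25 to 36 and 49 to 60, and -23.7 and -13.7 in the sets numbered 13 to 24 and 37 to 48. The ranges of the former sets and the latter did not overlap. The control libraries lay in sets 2, 3, 4 and 5 and the 4 g/L libraries in sets 1, 2, 3 and 4.

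**Figure D3:**
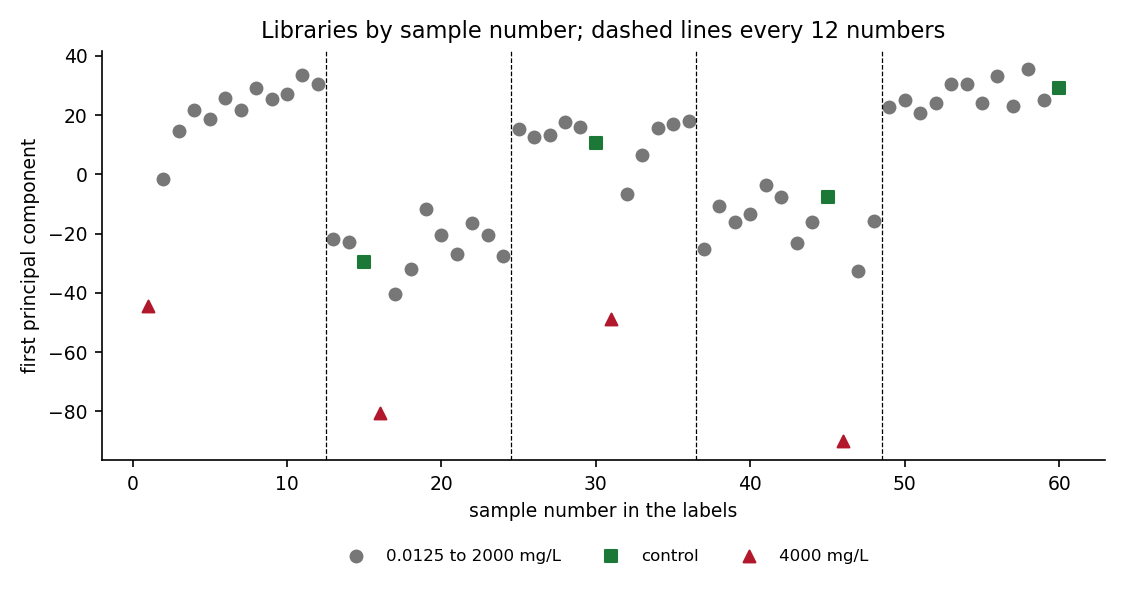
The first principal component of the 60 libraries against the sample number in the labels, with dashed lines after every 12 numbers. Controls are squares, 4000 mg/L libraries are triangles and the other concentrations are circles; the component changes level at the dashed lines, and the 4000 mg/L libraries lie lowest in each set that holds one.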

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

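The tests of explanations in this part were all chosen after the results were seen; the test of 1 library against the other 3 of its group was not. That test compared the gap between the extreme library and its nearest neighbour with the whole range of the group, for the reads of 15 groups and for 228 gene groups. Chance marks about 1 in 20 groups, and 1 of the 15 and 10 of the 228 (4.39%) were marked.

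The reads of replicate 4 at 125 mg/L stood at 4522107 against 1279331 to 1464292 in the other libraries of its group (gap over range 0.942962). Among genes at 4 g/L, dod-3 was highest in replicate 2 (gap over range 0.903197), pck-1 was highest in replicate 2 (0.947531), unc-22 was highest in replicate 4 (0.903812) and rps-24 was highest in replicate 3 (0.861392). Among genes in the controls, ubl-5 was lowest in replicate 4 (0.901122), lin-42 in replicate 2 (0.869526), nhr-31 in replicate 2 (0.868793), cyb-3 in replicate 1 (0.852784), ric-19 in replicate 1 (0.854264) and pas-2 in replicate 1 (0.878045).

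The libraries split by runs of 12 sample numbers, a pattern found in the data. Of 12 ways to place the boundaries of the runs, 1, the one used, gave the smallest median residual SD (0.335, against 0.339 for the next and 0.375 with no set term). On the reads over the size factor, libraries of 1 set with different replicate numbers had a mean correlation of 0.178, which argues against the replicate number as the whole cause. Libraries that shared a number and lay in different sets had one of -0.105. Each number joins a set of high level to a set of low level on the first component. That value therefore cannot decide on the replicate number. With log10 of the reads as a term, 99.7% of the range of the sets on the first component was left (47.4, against 47.6 without it), which argues against depth as the whole cause. Runs of 12 libraries handled together may be the source, and no biological explanation was tested. Which step such runs shared is not known. Sample numbers follow the concentration within each replicate number, while concentrations were placed at random on the 12-well plates, so a run need not be a plate of worms.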

How the results depend on the processing

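The set term, fits on the recovered reads, voom, thinned reads, fits without 3 libraries of large residual spread, and the replicate block combined with these were chosen after seeing the data. For a table of counts the main test was planned with edgeR. The deposited values are not counts, so limma was used as planned for such a table. Neither edgeR nor DESeq2 was run on the recovered reads either, where voom was used. Where a count moved, the cause was not tested, except that fits on fewer libraries or reads have less to test with. Of the results for named genes under all alternatives, 3392 had the same direction and side of the threshold, 272 lost the call and 1 turned: the log2 fold change of dhs-26 per rank of concentration was 0.0079842 without 4, 2 and 1 g/L. Of the results for lists at 4 g/L, 540 were the same, 16 gained and 20 lost the call.

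Counts of called genes that moved by over 1.5 times were, with library weights, 1 at 0.0125 mg/L, 4 at 500 mg/L, 76 at 2 g/L and 88 for the trend. Fits on the 8 libraries of a comparison called 6 at 1 g/L and 1131 at 4 g/L. voom on the reads called 1781 at 4 g/L and 156 for the trend. Reads over the size factor gave 2 at 250 mg/L and 304 for the trend, and with the set term 2 and 1069. Thinned reads with the set term gave 1 at 7.81 mg/L, 0 at 250 mg/L (294 at an unadjusted p of 0.05 and 1 called in the limma fit as reported), 1 at 500 mg/L, 6 at 1 g/L, 31 at 2 g/L, 1076 at 4 g/L and 336 for the trend. The trend held 1169 genes with the set term on deposited values, 106 over log10 of the concentration, 32 without 4 g/L and 2 without 4, 2 and 1 g/L.

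Leaving out 1 library at a time gave 0 to 1 genes at 1.56 mg/L (1 without control replicate 1), 1 to 2 at 250 mg/L (2 without replicate 4), 2 to 3 at 500 mg/L, 13 to 17 at 1 g/L, 36 to 64 at 2 g/L and 1303 to 3345 at 4 g/L (1303 without replicate 4 and 1817 without control replicate 2), and 0 at the other concentrations. For the trend, leaving out the 15 libraries of 1 replicate number gave 125 to 1697 genes (1588, 125, 1697 and 226 without replicates 1, 2, 3 and 4).

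The replicate numbers showed no clear pairing of the samples. On the reads over the size factor, deviations of libraries with the same number had a mean correlation of 0.0941 and a lowest one of -0.317, with 51.7% of the 420 pairs over 0.1. Pairs that shared neither number nor set had a mean of -0.0675, and pairs with the same number in different sets one of -0.105. Each number spans sets of different level, which could hide a pairing. In the deposited values the number had been adjusted for, so their correlation (mean -0.0352) does not bear on it. With the replicate number as a block 2760 genes were called at 4 g/L, 49 at 2 g/L, 15 at 1 g/L and 595 for the trend. With the block and reads over the size factor 2 were called at 250 mg/L, and with the block, the set term and reads over the size factor 11 at 1 g/L.

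Counts of called lists were 0 with an estimated correlation and 0 with fry at each concentration from 0.0125 to 500 mg/L, 0 with an estimated correlation at 1 g/L (1 with the set term as well, and 1 with fry) and for the trend (10 with fry), 2 and 3 at 2 g/L and 1 and 24 at 4 g/L. With the set term on the reads 1 list was called at 1.56 mg/L, 2 at 7.81, 125 and 500 mg/L, and 3 at 250 mg/L and 1 g/L. With the set term on deposited values 2 were called at 1.56 mg/L, 3 at 7.81 mg/L, 1 at 15.6 mg/L and 5 at 62.5 mg/L. Without the 3 libraries of large residual spread 3 were called at 31.3 mg/L and 5 at 62.5 mg/L. Leaving out 1 library gave, from 0.0125 mg/L up, 0 to 3, 3 to 12, 3 to 11, 1 to 7, 1 to 8, 0 to 5, 2 to 8, 2 to 7, 1 to 8, 1 to 7, 2 to 7, 1 to 6, 5 to 10 and 13 to 16 lists, and leaving out 1 replicate number 10 to 17 for the trend. Reads of 0 made up 1.07% of the values, and whether depth limited genes of few reads most was not tested.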

Other observations

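The tests of explanations in this part were all chosen after the results were seen, and so were the genes of the next paragraph.

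Of 8 genes listed as possible targets of NHR-49, a nuclear receptor that regulates fatty acid metabolism, 2 fell at 4 g/L: the desaturase gene fat-7 at -1.51 ± 0.38 (SE, limma adjusted p = 0.00301) and the flavin monooxygenase gene fmo-2 at -1.55 ± 0.38 (limma adjusted p = 0.00243). Of the 6 that were not called, acs-2 stood at -0.82 ± 0.55, fat-5 at -0.53 ± 0.36, ech-1.1 at -0.16 ± 0.28, acs-22 at -0.08 ± 0.19, fat-6 at 0.04 ± 0.25 and cpt-5 at 0.23 ± 0.28. As a set with the set term the 8 genes gave p = 0.172 with an estimated correlation and p = 0.146 with the preset one, so a lower activity of NHR-49 may or may not be part of the pattern and cannot be told apart from other causes with 8 genes.

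At 4 g/L 64 of 96 collagen and 26 of 80 sperm genes rose, and 4 of 6 vitellogenin, 17 of 27 oocyte and 22 of 31 proteasome genes fell, while none of these lists was called with an estimated correlation (adjusted p from 0.249 to 0.452 with an estimated correlation). Differences between sets of 12 are argued against as the whole cause, since 140 of the 142 called members (98.6%) kept call and direction with the set term. The median size of their log2 fold changes was 1.33 after thinning all libraries to 1 depth and 1.31 before. Thinning keeps the expected ratio of reads, so this argues only against unequal read numbers at 4 g/L. It does not decide on other causes that come with lower depth. A candidate explanation is an earlier stage of development at 4 g/L, which was not tested, since no staged reference was used. Over 36 lists, the median along the axis that separates the sets, taken from the 36 libraries at the 9 concentrations without calls, was related to the median change at 4 g/L (Pearson r = 0.625, permutation p = 0.00116; Spearman rho = 0.529, permutation p = 0.00103), with r = 0.500 without the sperm and collagen lists. No table ties that axis to stage and lists are not independent, so this relation decides nothing on stage, and a direct effect on these tissues stays open as well.

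cyp-13A7 and cyp-13A6 rose with concentration, and the lowest of the lower bounds of the counting interval of the fold of cyp-13A7 between 4 g/L and the control within a set was 7.47 on the log2 scale, which argues against differences between sets. If all cyp-13A6 reads were shared from cyp-13A7, the ratio of cyp-13A6 to cyp-13A7 reads would stay fixed. It grew 3.42 times, from 13.4% ± 2.82 (SD, n = 4) at 500 mg/L to a mean of 45.9% at 4 g/L (38.1% to 53.8% over 4 libraries). This ratio cannot decide on reads shared in part, or shared with cyp-13A4 and cyp-13A5, which also rose. At 250 mg/L, with 1 to 4 reads of cyp-13A6 per library, the ratio was 25.5% ± 13.2 (SD, n = 4), so it did not grow at every step. cyp-13A7 rose at each step in 4 of 4 sets, of which 3 span 250 mg/L to 4 g/L and the other holds 1, 2 and 4 g/L. A response of these genes to the concentration is the hypothesis these values leave, found and tested on the same libraries. How much of it belongs to each copy stays open.

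Other splits of the 8 libraries of a comparison bear on each count of genes. The real split gave the highest count at 250 mg/L (1 gene, highest other split 0, 1 of 35 splits as large), 500 mg/L (2, 1), 1 g/L (17, 1), 2 g/L (50, 17) and 4 g/L (2932, 2335). At 2 and 4 g/L the highest other split still held treated replicates 1, 2 and 4 together, joined by control replicate 1. Its other side was the remaining controls and treated replicate 3. It therefore kept much of the treatment difference and does not show what chance alone gives. At 4 g/L the median count of the other splits was 0. A share of 1 in 35 is the smallest that 35 splits can give. It was not adjusted over the concentrations, so chance is made less likely there and is not excluded. For the trend 2 of 100 orders were as large as the real one (676 genes), with 845 genes in the other of these. The orders ignored the sets; with the set term and orders drawn within sets, 1 of 100 was as large (1069 genes, highest other 1). With the set term the highest other count at 4 g/L was 460 against 3076, from the same split that gave 2335. At 250 mg/L with the set term 2 of 35 splits were as large (2 genes, highest other 3), so chance cannot be excluded there with it. At each of the 9 lower concentrations all 35 splits were as large as the count of 0, with highest other splits of 203, 665, 0, 17, 0, 0, 2, 1 and 1 from the lowest concentration up. The splits with 203 and 665 genes put sets 2 and 4 against sets 3 and 5, which points to the structure of the sets.

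For the counts of lists called with the preset correlation chance cannot be excluded at any concentration. These splits ignored the sets, and none was made for lists with the set term. The counts of other splits may therefore hold differences between sets, and at the high concentrations part of the treatment difference. From the lowest concentration up, the splits as large were 32, 8, 7, 28, 10, 33, 21, 28, 20, 13, 22, 35, 11 and 4 of 35, the counts 1, 10, 9, 4, 7, 2, 8, 3, 5, 6, 5, 1, 9 and 14, and the highest other splits 15, 12, 11, 10, 10, 11, 13, 11, 13, 11, 12, 14, 15 and 17. For the trend 7 of 100 splits were as large (13 lists, highest other 16).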
